A study of Drosophila melanogaster with 7 samples.

How the data were processed

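Nuclear RNA of adult Drosophila heads was sequenced by the authors in libraries of nuclei tagged by 3 GAL4 lines (R57C10, OK107 and Tdc2). A further library was of the whole dissected brain, the only sample not taken from tagged nuclei. Libraries were made with a NuGEN Ovation kit and read as 50-base Illumina reads, per the labels. The labels name CASAVA 1.8, TopHat 1.4.0, Cuffdiff 1.3.0 and bedtools 2.15, with genome build dm3. FPKM values per gene and per isoform were estimated by the authors with Cuffdiff and set to NA where its status was not OK, per the file headers. Adjusted p-values (q-values) and log2 fold changes of pairs of libraries were made by the authors with Cuffdiff, and a q-value is listed only where it is under 0.05. Of these deposited calls, R57C10 against whole brain had 719 fly genes higher in whole brain and 860 lower, and OK107 a against OK107 b had 14 higher in b and 4 lower.

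The gene table lists 15551 fly genes and 92 spike-in species, and 25609 isoforms have values in a table of their own. Of the fly genes 683 have no value in at least 1 library and 475 in any. The tables hold 6 libraries for the 7 samples in the labels, with 1 of the 2 R57C10 samples, and whether libraries were pooled is not stated. The same library has identical values in every comparison it enters, and repeats were not used. Current symbols of 14782 genes were matched by their CG or CR numbers; genes are named as in the tables. The annotation at hand is of another genome build, so no coordinates are given. Strand was not known, so overlapping genes and nearly identical copies are uncertain. Read counts and raw reads were not analysed here.

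The depth of a library was read from the steps between low FPKM values of 5628 genes with 1 isoform of at least 600 bases. Implied reads were 36.5 M in R57C10, 27.5 and 24.0 M in OK107 a and b, 23.7 and 38.8 M in Tdc2 a and b, and 60 M in whole brain. Between 64.5% and 72.4% of the values examined lay within 0.2 of a whole read at these steps. These depths are estimates.

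Differences between groups were tested with limma 3.58.1 in R 4.3.3 (trend and robust eBayes) on log2(FPKM + 1), which understates differences of genes at low levels. Genes with at least 1 FPKM in at least 2 libraries were kept, p-values were adjusted by Benjamini-Hochberg, and a gene passed under 0.05. The design had been written for counts or FPKM, and FPKM was the unit found. OK107, Tdc2 and R57C10 were fitted together on 5 libraries, with all 6 for R57C10 against whole brain, and 2 residual degrees of freedom in each fit. Lone libraries were assumed to vary like the OK107 and Tdc2 pairs, which are unlike. Between 100 and 1000 implied reads per gene the SD of log2 ratios was 0.19 within the OK107 pair and 0.49 within the Tdc2 pair, and median squared differences were 1.57 and 8.45 times those of counting alone. On simulated data of the same sizes, between 13% and 60% of 2-fold changes and between 84% and 99% of 4-fold changes were recovered, and between 1.85% and 7.43% of calls were false. The simulation gave a gene the same spread in every library, drew genes independently and changed only genes above a minimum level. The real pairs differ in spread, so these rates do not give the share of false calls in the data.

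The comparisons, the filter, the 29 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera in limma, with a preset correlation of 0.01 and adjustment over all lists and comparisons. Camera was repeated with a correlation estimated for each list, and fry was run as another test, of each list against no change rather than against other genes. The repeat of camera draws on the 2 residual degrees of freedom of the fit. A list that fails it is therefore not evidence against its call. Lists of nuclear-retained noncoding RNA genes and transgene marker genes were too small. The lists hold markers of cell types, genes of transmitters, receptors and channels, transcription factors, clock, heat shock, immune, ribosomal protein and mitochondrially encoded genes. Isoform use was tested with limma diffSplice (Simes, gene level) on genes with at least 2 isoforms at 1 FPKM in at least 2 libraries. On simulated data 75.0% of changed genes were recovered with 4.46% of calls false, and 16.4% false where each isoform had its own spread. Spread was the same in every library here too.

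Genes named are those with the largest differences each way that passed, had all libraries of a group above all of the other and a mean of at least 10 FPKM, up to 12 each way; genes known only by a CG or CR number are named only among the 3 largest. Members of each list with the smallest p, up to 4, or all members of lists of 8 or fewer, are also named, with the genes that check the labels. Alternatives were median centring, quantile normalization, other filters and pseudocounts (0.1 and 5), limma without trend and robust, other sets of libraries, no mitochondrially encoded or ribosomal RNA genes, a 2-fold minimum, and leaving out each OK107 and Tdc2 library. Spike-in status and date tag as terms, and the lists under other scalings, were added after the data were seen. Only the Tdc2 pair spans both date tags, so the date tag term carries that pair's own differences into comparisons among the tagged nuclei. It leaves 1 residual degree of freedom, from the OK107 pair. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.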

Results

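The libraries of tagged nuclei measured nuclear RNA from heads of adult Drosophila. Nuclei were isolated from flies in which a GAL4 line drove a tagged nuclear membrane protein (unc84-GFP) in chosen cells. R57C10 marks all mature neurons, OK107 marks primarily Kenyon cells (the intrinsic neurons of the mushroom body), and Tdc2 marks primarily octopaminergic neurons. A library of the whole dissected brain, with all cells of the brain and not taken from tagged nuclei, was the remaining group. Of the 7 samples in the labels, 6 have a library in the gene table: 1 of R57C10, 2 of OK107 (a and b), 2 of Tdc2 (a and b) and 1 of whole brain, and all comparisons rest on these. Levels were in FPKM (fragments per kilobase of transcript, scaled to library size). Steps between low values implied between 23.7 and 60 M reads per library, at which 1 read on a 1-kilobase transcript was worth 0.0167 to 0.0422 FPKM. Between 8486 and 9460 genes reached 1 FPKM in a library.

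Across genes, log2 levels of the OK107 pair correlated at 0.995 and those of the Tdc2 pair at 0.978 (genes are not independent replicates). R57C10 correlated with OK107 at 0.937 and 0.933 and with Tdc2 at 0.895 and 0.898. Whole brain correlated with R57C10 at 0.802, with OK107 a and b at 0.8255 and 0.8287, and with Tdc2 a and b at 0.8884 and 0.8504. Whole brain was thus closest to the Tdc2 libraries. R57C10 and whole brain have 1 library each and are assumed to vary like the OK107 and Tdc2 pairs, so every p-value below measures only the spread between these samples. These pairs are unlike: between 100 and 1000 implied reads per gene the SD of log2 ratios was 0.19 in the OK107 pair and 0.49 in the Tdc2 pair. The pooled spread lies between them. The libraries also differ in preparation. Spike-in RNA was absent from OK107 a and Tdc2 a and present in the other 4 libraries. Column names carry an earlier date tag for both OK107 libraries and Tdc2 a, and a later tag for Tdc2 b, R57C10 and whole brain. OK107 and R57C10 therefore share no date tag. The OK107 pair shares 1 date tag, while the Tdc2 pair spans both. Whether the OK107 libraries came from separate preparations is not known here. If they did not, the pooled spread and the p-values are too small.

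Genes that define the GAL4 lines were read first. Tdc2 (CG30446), the tyrosine decarboxylase gene whose promoter names the line, was at 110.1 and 90.3 FPKM in the Tdc2 libraries and between 2.68 and 3.01 in the other 4. Tbh (CG1543), which encodes the enzyme that makes octopamine, was at 1668 and 2159 in Tdc2, 37.1 in R57C10, 38.3 in whole brain, and 16.6 and 16.9 in OK107. OK107 is an insertion near ey (CG1464), a mushroom body transcription factor gene, and ey was at 248 and 259 in OK107, 35.9 in R57C10, and no higher than 12.8 in Tdc2 and whole brain. The neuronal genes elav and n-syb were abundant in all 6 libraries, from 153 to 277 for elav and from 934 to 1541 for n-syb.

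**Figure D1:**
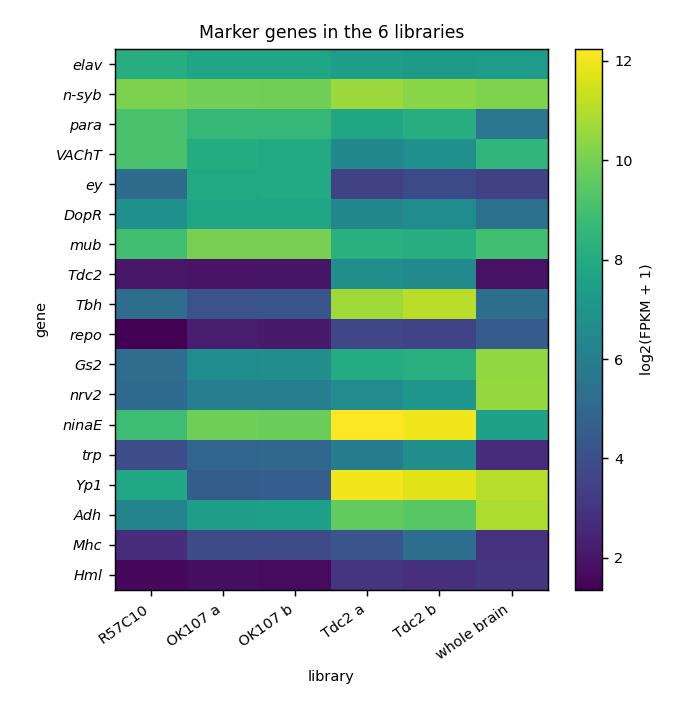
Levels of marker genes (log2(FPKM + 1), colour) in each of the 6 libraries (columns); rows are neuronal, Kenyon cell, octopaminergic, glial, photoreceptor, fat body, muscle and hemocyte genes. ey stands out in the OK107 pair, at 248 and 259 FPKM, and Tdc2 and Tbh in the Tdc2 pair.

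The comparison of OK107 with R57C10 asks what sets Kenyon cells apart from neurons at large. Values in parentheses after gene names are log2 fold changes of FPKM + 1, the group named earlier over the other. ey was higher by 2.78 (SE 0.15, adjusted p = 0.00209). CG10251 (now prt), which encodes a vesicular transporter of Kenyon cells, was at 54.5 and 59.4 FPKM against 10.8, a difference of 2.30 (SE 0.14). dac, another transcription factor gene, was higher by 1.47 (SE 0.13), and rut, the adenylyl cyclase gene required for olfactory memory, by 1.21 (SE 0.12). Among the Kenyon cell markers 16 of 20 were higher and 4 did not pass (18 higher adjusted over the list alone). After median centring 10 were higher. Their median lay 0.64 above that of all genes on the log2 scale (camera adjusted p = 9.36e-06, and adjusted p = 0.429 with an estimated correlation). No list in any comparison passed with an estimated correlation. That form of camera draws on the 2 residual degrees of freedom of the fit, so it has little power here. The Kenyon cell list lost its call at an estimated correlation of -0.031. Such a failure therefore does not show that correlation between genes made the call. Pka-R2 (1.28), Pka-C1 (1.10) and Pka-R1 (0.74), which encode protein kinase A subunits, were higher. Of the cAMP and memory genes as a list, 6 of 17 were higher, 1 lower and 10 did not pass (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.621).

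Receptors for amines differed by subtype. Dopamine receptor genes DopR2 (73.0 and 68.1 against 23.9 FPKM, 1.52, SE 0.15), D2R (0.86) and DopR (0.95) were higher in OK107, while DopEcR, which also binds ecdysteroids, was lower (-0.61). The list did not pass (adjusted p = 0.392). Of 4 tested, 3 were higher and 1 lower (3 higher and 1 lower adjusted over the list alone). After median centring 1 was higher and 1 lower, and after quantile normalization 3 and 1. Among serotonin receptors 5-HT1B was higher (0.90) and 5-HT7 (-1.3) and CG42796 (now 5-HT2B, -1.02) were lower. Of 5 tested, 1 was higher, 2 lower and 2 did not pass (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.105). In the list of octopamine and tyramine receptors Oamb was higher (0.75), and Octbeta2R (-1.10, SE 0.11), CG7431 (-0.65) and Octbeta3R (-0.64) were lower. Of the octopamine and tyramine receptors 1 of 8 was higher, 3 lower and 4 did not pass (1 higher and 3 lower adjusted over the list alone), and the list lay below other genes (camera adjusted p = 0.00496, and adjusted p = 0.532 with an estimated correlation). After median centring 0 were higher and 4 lower, and after quantile normalization 0 and 3.

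Peptide genes gave some of the largest differences. The insulin-like peptide genes Ilp2 (396 and 434 against 26.0 FPKM, 3.94, SE 0.12, adjusted p = 0.00143), Ilp3 (3.56, SE 0.15) and Ilp5 (4.01, SE 0.18), which are made by neurosecretory cells of the brain, were higher in OK107. So was Dh (now Dh44), a diuretic hormone gene, at 839.6 and 811 against 82.8 FPKM (3.30, SE 0.13). Ilp2, Ilp3 and Ilp5 were also lower in R57C10 than in whole brain, as were 21 of 29 neuropeptide genes, with 2 higher. Their rise over R57C10 is therefore not separated from low levels in R57C10. In OK107 the Ilp2, Ilp3 and Ilp5 genes were higher than in Tdc2 as well. The tachykinin gene Tk (-2.27, SE 0.16) and hug (-1.91, SE 0.25) were lower. Of the neuropeptide genes 10 of 28 were higher, 4 lower and 14 did not pass (10 higher and 5 lower adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.621). Both Cha, the choline acetyltransferase gene, (-1.35, SE 0.17) and VAChT, the vesicular acetylcholine transporter gene, (-1.11, SE 0.19) were lower in OK107. Of the cholinergic neuron genes 2 of 3 were lower and 1 did not pass (2 lower adjusted over the list alone, camera adjusted p = 0.000614, and adjusted p = 0.466 with an estimated correlation). The transcription factor genes of other neuron types scro (-2.64, SE 0.11), acj6 (-3.11, SE 0.15) and ap (-2.12, SE 0.14) were lower. Of the neuronal transcription factors 10 of 48 were higher, 18 lower and 20 did not pass (10 higher and 18 lower adjusted over the list alone, camera adjusted p = 2.61e-05, and adjusted p = 0.429 with an estimated correlation).

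Several genes on none of the lists were far higher in OK107. GV1 was at 163 and 168 FPKM against 2.89 (5.42, SE 0.22), PebIII at 112 and 136 against 4.30 (4.55, SE 0.15), vir-1 was higher by 3.85 (SE 0.13) and emp, a scavenger receptor gene, by 3.80 (SE 0.21). mthl8 was listed at 0 in R57C10 and both Tdc2 libraries, at 19.8 and 20.7 in OK107 and at 20.3 in whole brain. The chitin-binding or cuticle genes Gasp (5.05), Acp1 (4.52), serp (4.14), verm (3.92) and CG7203 (5.01) and the peptide precursor gene Nplp3 (4.24) passed with wide errors (SE 0.55 to 1.04, Gasp and Acp1). Their levels in the Tdc2 pair were also unequal, such as 16.7 and 90.6 FPKM for CG7203. Lower in OK107 were the yolk protein genes Yp1 (22.6 and 23.7 against 227 FPKM, -3.23, SE 0.15), Yp2 (-2.76) and Yp3 (-2.33), which are expressed mainly in females, the histamine receptor gene ort (-2.42), Sox102F (-2.12), AlstR (-1.79), y (-1.59) and CG13636 (-3.74). w was higher (2.42).

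Of the pan-neuronal genes 2 of 20 were lower and 18 did not pass (none passed adjusted over the list alone), and the list lay -0.55 from all genes (adjusted p = 2.54e-07, and adjusted p = 0.429 with an estimated correlation). Of these 17 were lower after median centring, 5 after quantile normalization, 8 with the date tag as a term and none with spike-in status as a term. Of the voltage-gated ion channels 1 of 19 was higher, 3 lower and 15 did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.37e-05, and adjusted p = 0.534 with an estimated correlation). Their median, relative to 0, moved from -0.32 to 0.01 with the date tag as a term, and 14 were lower after median centring. elk was higher (1.14) and SK (-0.76), Ih (-0.74) and qvr (-0.79) were lower. Grd was the furthest of the GABA and glutamate receptors (-1.82). Of 13 tested, 1 was higher, 2 lower and 10 did not pass (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0018, and adjusted p = 0.549 with an estimated correlation). Of the acetylcholine receptors 1 of 12 was lower and 11 did not pass (none passed adjusted over the list alone, camera adjusted p = 0.0866). Photoreceptor and phototransduction genes were higher, with retinin (3.35) and Rh5 (2.09) furthest. Of 28 tested, 15 were higher and 13 did not pass (15 higher adjusted over the list alone, camera adjusted p = 0.0251, and adjusted p = 0.431 with an estimated correlation). Among glial genes 8 of 14 were higher and 6 did not pass (9 higher adjusted over the list alone, camera adjusted p = 0.0608). After median centring or quantile normalization 3 were higher, and 11 with the date tag as a term. Among fat body genes 3 of 13 were higher, 3 lower and 7 did not pass (3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00695, and adjusted p = 0.431 with an estimated correlation). Among Hox genes 2 of 4 were lower and 2 did not pass (2 lower adjusted over the list alone, camera adjusted p = 0.00321, and adjusted p = 0.431 with an estimated correlation).

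The lists of muscle genes (3 of 18 were higher and 15 did not pass, 1 higher adjusted over the list alone), hemocyte genes (7 of 7 did not pass, none passed adjusted over the list alone), dopamine serotonin and histamine neuron genes (3 of 7 were higher and 4 did not pass, 3 higher adjusted over the list alone), GABAergic neuron genes (3 of 3 did not pass, none passed adjusted over the list alone), octopamine and tyramine synthesis and transport (1 of 3 was lower and 2 did not pass, 1 lower adjusted over the list alone), circadian clock genes (4 of 10 were higher, 1 lower and 5 did not pass, 7 higher and 1 lower adjusted over the list alone), antimicrobial peptide genes (8 of 8 did not pass, none passed adjusted over the list alone), immediate early candidates (2 of 8 were higher and 6 did not pass, 2 higher adjusted over the list alone) and heat shock genes (8 of 15 were higher and 7 did not pass, 11 higher adjusted over the list alone) did not pass camera. In these the clock genes vri (1.63), Clk (1.89) and tim (1.28) and the heat shock genes Hsp22 (2.29, SE 0.17), Hsp26 (1.42) and Hsc70-3 (1.20) were higher, and Pdfr was lower (-1.41). Of 86 ribosomal protein genes 31 were higher and none lower as deposited (39 higher adjusted over the list alone), but after median centring none was higher and 1 was lower (adjusted p = 0.00135, and adjusted p = 0.622 with an estimated correlation). Under quantile normalization 13 were higher, and 48 with the date tag as a term.

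Counts of other lists in this comparison also moved by more than 1.5 times and by at least 3 genes. The date tag term is estimated through the Tdc2 pair, so differences within that pair enter it. Against R57C10, muscle genes lay 2.33 above all genes in Tdc2 b and 1.28 in Tdc2 a. The moves under this term are not separated from such gaps. With the date tag as a term 17 of 18 muscle genes were higher, and their median above all genes moved from 0.37 to 1.27. With this term 3 of 3 GABAergic neuron genes, 6 dopamine serotonin and histamine neuron genes, 6 fat body genes, 3 acetylcholine receptors, 5 GABA and glutamate receptors, 3 antimicrobial peptide genes and 5 immediate early candidates were higher. On the other side 8 neuropeptide and 4 heat shock genes were then lower. Median centring left 9 photoreceptor genes, 5 neuronal transcription factors and 3 cAMP and memory genes higher. It put 3 photoreceptor genes, 5 cAMP and memory genes, 6 fat body genes, 8 neuropeptide genes, 4 acetylcholine receptors and 7 GABA and glutamate receptors lower. Under quantile normalization 4 heat shock genes were higher.

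In this comparison 2388 of 9585 genes passed in limma (adjusted p under 0.05), 2047 higher in OK107 and 341 lower, and 1013 and 133 of these differed at least 2-fold on the log2(FPKM + 1) scale. The split into higher and lower genes depends on the scaling. The median of all genes lay 0.30 higher in OK107 as deposited, and the split was 792 higher and 1562 lower after median centring and 759 and 663 after quantile normalization. Relative to the median of all genes, quantile normalization turned the cAMP and memory list from -0.14 to 0.01 and the immediate early list from -0.05 to 0.09. The date tag as a term turned the serotonin receptors from -0.36 to 0.11, the antimicrobial list from -0.32 to 0.07, the cAMP and memory list to 0.02 and the immediate early list to 0.20. Spike-in status as a term turned the immediate early list to 0.02. None of these lists had passed camera. Median centring moves all genes alike and so leaves these relative medians in place. The count also rests on single libraries: it was 544 without OK107 replicate a, 481 without OK107 replicate b, and 5706 and 5712 without Tdc2 replicate a and b. No pair of libraries compares these groups within a date tag; with the tag as a term, estimated through the Tdc2 pair, 3548 genes passed, 3061 higher and 487 lower.

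**Figure D2:**
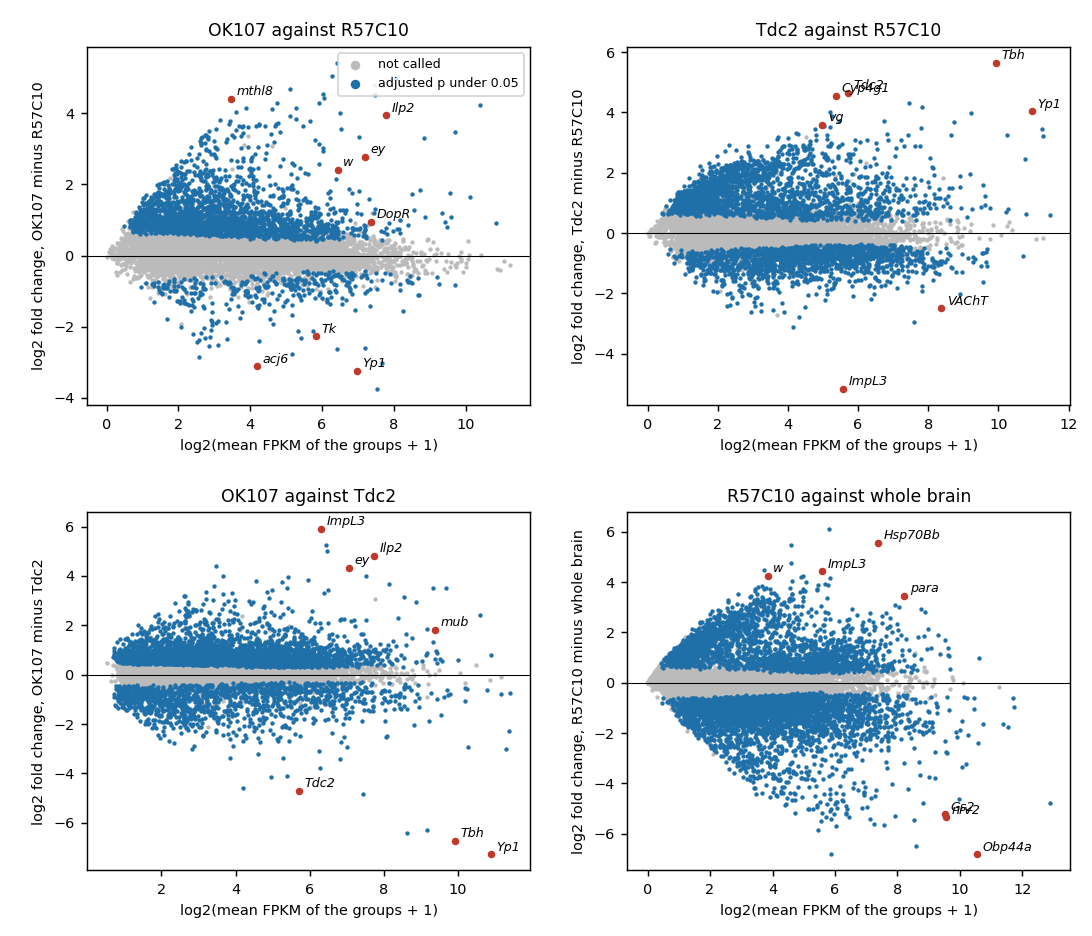
Log2 fold change of each gene (points) against its mean level for the 4 comparisons; blue points passed an adjusted p under 0.05 in limma and red points are named genes. Tbh and Yp1 lie far above 0 in Tdc2 against R57C10 and far below 0 in OK107 against Tdc2.

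The comparison of Tdc2 with R57C10 asks what sets octopaminergic neurons apart from neurons at large. Tbh was higher by 5.64 (SE 0.18, adjusted p = 0.000987) and Tdc2 by 4.65 (SE 0.17, adjusted p = 0.000987). VGlut, the vesicular glutamate transporter gene, was higher by 0.84 (SE 0.12). Of the list of octopamine and tyramine synthesis and transport genes 3 of 3 were higher (3 higher adjusted over the list alone, camera adjusted p = 0.00281, and adjusted p = 0.431 with an estimated correlation). The acetylcholine genes VAChT (85.5 and 113 against 559 FPKM, -2.50, SE 0.19), CG7708 (now ChT, -1.72, SE 0.18) and Cha (-1.48, SE 0.17) were lower (3 of 3 were lower, 3 lower adjusted over the list alone, camera adjusted p = 0.0046, and adjusted p = 0.502 with an estimated correlation). In the list of dopamine serotonin and histamine neuron genes Hdc (1.99) and Pu (1.95) were higher and DAT (-1.47) and Ddc (-0.57) lower. Of 7 tested, 2 were higher, 2 lower and 3 did not pass (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.951). In the same libraries the photoreceptor list lay 2.16 above all genes, and the rises of Hdc and Pu are not separated from that. Of the GABAergic neuron genes 1 of 3 was higher, 1 lower and 1 did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.726). Their median relative to all genes was -0.11 and turned to 0.05 under quantile normalization, and it was 0.00 with the date tag as a term.

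Transcription factor and peptide genes went both ways, and neither list passed. vg, a wing and muscle selector gene, was at 62.4 and 52.3 FPKM against 3.82 (3.59, SE 0.18), and dsx, the sex-determination gene, at 14.3 and 14 against 3.27 (1.82, SE 0.15). scro (-1.61), ap (-1.75) and toy (-1.3) were lower. Of the neuronal transcription factors 15 of 48 were higher, 17 lower and 16 did not pass (17 higher and 19 lower adjusted over the list alone, camera adjusted p = 0.218). Among Hox genes Antp (1.3), Dfd (1.31) and pb (0.90) were higher and Scr did not pass (adjusted p = 0.0441, and adjusted p = 0.466 with an estimated correlation). Of 4 tested, 3 were higher and 1 did not pass (3 higher adjusted over the list alone). The drosulfakinin gene Dsk (185 and 210.4 against 14 FPKM, 3.72, SE 0.13), Ast-C (2.79, SE 0.14) and capa (2.04, SE 0.21) were higher, Tk (-2.08) and Ilp1 (-1.87) were lower. Of the neuropeptide genes 7 of 28 were higher, 8 lower and 13 did not pass (7 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.668).

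Most channel genes and part of the receptor genes were lower. In the same libraries the photoreceptor, fat body, muscle and glial lists lay 2.16, 2.13, 1.84 and 1.63 above all genes, so these falls are not separated from that rise. In the list of voltage-gated ion channels slo (-1.21, SE 0.15), para (223 and 282 against 547 FPKM, -1.12, SE 0.17), Ih (-1.03) and Shal (-0.92) were lower. Of 19 tested, 16 were lower and 3 did not pass (17 lower adjusted over the list alone, camera adjusted p = 9.05e-07, and adjusted p = 0.509 with an estimated correlation). Of the acetylcholine receptors, with gfA at -1.12 and nAcRbeta-64B at -1.10, 1 of 12 was higher, 7 lower and 4 did not pass (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00135, and adjusted p = 0.502 with an estimated correlation). GABA-B-R1 (-1.34), GABA-B-R3 (-1.16) and Grd (-2.03) were lower among GABA and glutamate receptors. Of 13 tested, 7 were lower and 6 did not pass (8 lower adjusted over the list alone, camera adjusted p = 0.000302, and adjusted p = 0.524 with an estimated correlation). The octopamine and tyramine receptor genes CG7431 (-1.40), Octbeta3R (-1.26), Oamb (-1.12) and Octbeta2R (-0.89) were lower. Of 8 tested, 4 were lower and 4 did not pass (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0251, and adjusted p = 0.596 with an estimated correlation). DopEcR was lower (-1.3, SE 0.14), as was D2R (-0.49). Of 4 tested, 2 were lower and 2 did not pass (2 lower adjusted over the list alone, camera adjusted p = 0.0313, and adjusted p = 0.466 with an estimated correlation). Of the serotonin receptors 2 of 5 were lower and 3 did not pass (2 lower adjusted over the list alone, camera adjusted p = 0.105). Of the pan-neuronal genes 1 of 20 was higher, 9 lower and 10 did not pass (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0441, and adjusted p = 0.444 with an estimated correlation), with stj (-1.26), unc-13 (-1.08) and Rdl (-0.96) lower. The activity-regulated gene Hr38 (-2.21, SE 0.17) and puc (-1.75, SE 0.11) were lower among immediate early candidates. Of 8 tested, 1 was higher, 6 lower and 1 did not pass (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.596 with an estimated correlation).

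Kenyon cell markers were lower, with ey (-1.56), dac (-1.33), toy (-1.3) and rad (-1.21) having the smallest p. Of 20 tested, 1 was higher, 12 lower and 7 did not pass (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 5.92e-05, and adjusted p = 0.429 with an estimated correlation). cAMP and memory genes went both ways (2 of 17 were higher, 6 lower and 9 did not pass, 2 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.108), with rut lower (-1.01) and Ac13E higher (1.37). ImpL3 (now Ldh), the lactate dehydrogenase gene, was at 1.62 and 1.54 FPKM in Tdc2 against 91.4 in R57C10 (-5.16, SE 0.12, adjusted p = 0.000773), and between them lay whole brain at 3.26. Also lower were ort (-3.12), the bone morphogenetic protein modulator gene cv-2 (-2.78), the opsin gene Rh7 (-2.46), dl (-2.07), Pvf3 (-2.03), CheB74a (-2.03), KP78b (-2.01) and CG13636 (-2.96).

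Genes of photoreceptors, which are sensory neurons, and of cells other than neurons were higher in Tdc2. The rhodopsin gene ninaE was at 4829.5 and 4054 FPKM against 469 (3.23, SE 0.15), retinin at 465 and 383 against 22.4 (4.18, SE 0.19), and Rh4 (3.89) and inaF-B (3.27) were also higher. Of the photoreceptor and phototransduction genes 21 of 28 were higher, 2 lower and 5 did not pass (22 higher and 4 lower adjusted over the list alone, camera adjusted p = 2.58e-07, and adjusted p = 0.429 with an estimated correlation). The fat body genes Yp1 (4104 and 3428 against 227 FPKM, 4.04, SE 0.15), Yp3 (3.98), Yp2 (3.67) and Adh (3.24) were higher. Of 13 tested, 10 were higher and 3 did not pass (11 higher adjusted over the list alone, camera adjusted p = 8.06e-07, and adjusted p = 0.429 with an estimated correlation). Cyp4g1, a gene of hydrocarbon-producing oenocytes, was higher by 4.56 (SE 0.30), and MtnA by 3.72 (SE 0.27). Among glial genes, with Gs2 (2.88), Glt (2.86) and repo (2.27) higher, 11 of 14 were higher, 1 lower and 2 did not pass (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.13e-05, and adjusted p = 0.466 with an estimated correlation). Among muscle genes, with Mlp60A (2.38) and fln (2.30) higher, 9 of 18 were higher and 9 did not pass (14 higher adjusted over the list alone, camera adjusted p = 0.000111, and adjusted p = 0.61 with an estimated correlation). Among hemocyte genes, with srp (1.96) and Cg25C (2.30) higher, 5 of 7 were higher and 2 did not pass (6 higher adjusted over the list alone, camera adjusted p = 0.00531, and adjusted p = 0.431 with an estimated correlation).

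Ribosomal protein genes were higher as well, such as RpLP0 (2.39, SE 0.12) and RpS2 (2.18, SE 0.12). Of 86 tested, 79 were higher, 1 lower and 6 did not pass (83 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.12e-23, and adjusted p = 0.431 with an estimated correlation). Of the antimicrobial peptide genes 3 of 8 were higher and 5 did not pass (4 higher adjusted over the list alone, camera adjusted p = 0.0458, and adjusted p = 0.622 with an estimated correlation). Of the circadian clock genes 7 of 10 were higher, 1 lower and 2 did not pass (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00968, and adjusted p = 0.431 with an estimated correlation), with tim (1.72), Clk (1.66) and vri (1.48) higher. Heat shock genes went both ways (5 of 15 were higher, 6 lower and 4 did not pass, 5 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.671), with Hsp23 higher (3.25, SE 0.29) and Hsp22 lower (-1.66, SE 0.17). Tdc2 b and R57C10 share date tag and spike-in status, and between these libraries alone the medians above all genes were 2.43 for photoreceptor, 2.08 for fat body, 1.88 for glial, 2.33 for muscle, 1.24 for hemocyte and 1.53 for ribosomal protein genes, and fell by 0.75 for voltage-gated ion channels and by 0.67 for Kenyon cell markers.

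In all, 3437 of 9585 genes passed in limma, 1979 higher in Tdc2 and 1458 lower, with 1295 and 520 of these at least 2-fold. After median centring the split was 1786 and 2272 and after quantile normalization 1631 and 1973. Lists moved as well, by more than 1.5 times and at least 3 genes. All 18 muscle genes and 6 antimicrobial peptide genes were higher, and 13 neuropeptide genes lower, with the date tag as a term. Spike-in status as a term gave 15 muscle genes, 6 antimicrobial peptide genes and 3 circadian clock genes higher, and median centring 3 circadian clock genes. The count was 2136 without OK107 replicate a, 2157 without OK107 replicate b, 5022 without Tdc2 replicate a and 5702 without Tdc2 replicate b.

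The comparison of OK107 with Tdc2 sets the 2 selected cell types against each other, each with 2 libraries. ey was higher in OK107 by 4.34 (SE 0.13, adjusted p = 0.000245), CG10251 by 3.42 (SE 0.11), dac by 2.80 (SE 0.11) and toy by 2.22 (SE 0.09). Of the Kenyon cell markers 19 of 20 were higher and 1 did not pass (20 higher adjusted over the list alone, camera adjusted p = 2.24e-07, and adjusted p = 0.429 with an estimated correlation). rut (2.22, SE 0.10), rad (1.81, SE 0.10) and Pka-C1 (1.48, SE 0.11) were higher among cAMP and memory genes. Of 17 tested, 9 were higher, 3 lower and 5 did not pass (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.392). All of the dopamine receptors DopR2 (1.92), D2R (1.35), DopR (1.24) and DopEcR (0.68) were higher in OK107 (adjusted p = 0.0175, and adjusted p = 0.444 with an estimated correlation). Of 4 tested, 4 were higher (4 higher adjusted over the list alone). Oamb was higher (1.87, SE 0.14) and CG18208 (now Octalpha2R) lower (-0.66). Of the octopamine and tyramine receptors 3 of 8 were higher, 1 lower and 4 did not pass (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.864). Of the serotonin receptors, with 5-HT1B higher (1.87) and 5-HT7 lower (-1.48), 2 of 5 were higher, 2 lower and 1 did not pass (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.688).

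The peptide genes Ilp5 (5.27, SE 0.15), Ilp3 (5.00, SE 0.12), Ilp2 (4.81, SE 0.10), Dms (myosuppressin, 1418 and 1618 against 153 and 112 FPKM, 3.52, SE 0.18), npf (3.35, SE 0.35) and Dh (2.93, SE 0.11) were higher in OK107 and hug was lower (-3.77, SE 0.20). Of the neuropeptide genes 9 of 28 were higher, 8 lower and 11 did not pass (11 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.791). ImpL3 gave the largest positive difference, at 158 and 152 against 1.62 and 1.54 FPKM (5.92, SE 0.10, adjusted p = 4.49e-05). Hsp22 (3.95, SE 0.13), Dgp-1 (3.53), GV1 (3.44) and Acp1 (3.99, SE 0.85) were also higher in OK107. On the other side lay Yp1 (-7.28, SE 0.12, adjusted p = 5.01e-05), Yp2 (-6.43), Yp3 (-6.31), Tbh (-6.74, SE 0.15), Tdc2 (-4.71, SE 0.14), the transcription factor genes dmrt99B (-4.59, SE 0.27) and vg (-4.15, SE 0.14), Cyp4g1 (-4.09), Rh4 (-3.36), the immune peptide gene IM2 (-3.11) and the elongation factor gene Ef1alpha48D (-2.95). The octopamine and tyramine synthesis and transport list lay lower in OK107 (3 of 3 were lower, 3 lower adjusted over the list alone, camera adjusted p = 0.000111, and adjusted p = 0.429 with an estimated correlation).

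Lists of other cells were lower in OK107 than in Tdc2. For photoreceptor and phototransduction genes 3 of 28 were higher, 21 lower and 4 did not pass (3 higher and 22 lower adjusted over the list alone, camera adjusted p = 2.66e-10, and adjusted p = 0.429 with an estimated correlation). For fat body genes 11 of 13 were lower and 2 did not pass (11 lower adjusted over the list alone, camera adjusted p = 2.04e-10, and adjusted p = 0.429 with an estimated correlation). For glial genes 2 of 14 were higher, 8 lower and 4 did not pass (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 5.92e-05, and adjusted p = 0.466 with an estimated correlation). For muscle genes 7 of 18 were lower and 11 did not pass (7 lower adjusted over the list alone, camera adjusted p = 2.28e-06, and adjusted p = 0.534 with an estimated correlation). For hemocyte genes 6 of 7 were lower and 1 did not pass (6 lower adjusted over the list alone, camera adjusted p = 0.000183, and adjusted p = 0.429 with an estimated correlation). All 4 tested Hox genes, pb (-2.18), Dfd (-1.82), Scr (-1.25) and Antp (-1.28), were lower (adjusted p = 0.000221, and adjusted p = 0.429 with an estimated correlation). Of 4 tested, 4 were lower (4 lower adjusted over the list alone). Of the ribosomal protein genes 1 of 86 was higher, 72 lower and 13 did not pass (1 higher and 78 lower adjusted over the list alone, camera adjusted p = 4.6e-33, and adjusted p = 0.431 with an estimated correlation). Of the antimicrobial peptide genes 5 of 8 were lower and 3 did not pass (5 lower adjusted over the list alone, camera adjusted p = 0.000352, and adjusted p = 0.502 with an estimated correlation). Of the voltage-gated ion channels, with slo (1.23) and elk (1.3) higher, 12 of 19 were higher and 7 did not pass (13 higher adjusted over the list alone, camera adjusted p = 0.0177, and adjusted p = 0.679 with an estimated correlation). Of the immediate early candidates, with Hr38 (2.02) and Mef2 (1.56) higher, 6 of 8 were higher, 1 lower and 1 did not pass (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0434, and adjusted p = 0.622 with an estimated correlation). Of the neuronal transcription factors 13 of 48 were higher, 21 lower and 14 did not pass (13 higher and 21 lower adjusted over the list alone, camera adjusted p = 0.00304, and adjusted p = 0.431 with an estimated correlation). The pan-neuronal (7 of 20 were higher, 6 lower and 7 did not pass, 7 higher and 6 lower adjusted over the list alone), acetylcholine receptor (9 of 12 were higher, 1 lower and 2 did not pass, 9 higher and 2 lower adjusted over the list alone), GABA and glutamate receptor (9 of 13 were higher and 4 did not pass, 9 higher adjusted over the list alone), cholinergic neuron (2 of 3 were higher and 1 did not pass, 2 higher adjusted over the list alone), heat shock (10 of 15 were higher, 3 lower and 2 did not pass, 11 higher and 3 lower adjusted over the list alone) and circadian clock (1 of 10 was higher, 2 lower and 7 did not pass, 1 higher and 1 lower adjusted over the list alone) lists did not pass camera. The balance of the pan-neuronal list depends on the scaling, with 2 higher and 9 lower after median centring and 9 higher and 2 lower after quantile normalization. Spike-in status as a term gave 7 higher and 3 lower. Of the heat shock genes 4 were higher and 4 lower after median centring, and 4 and 3 after quantile normalization.

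Here 4631 of 9585 genes passed in limma, 3290 higher in OK107 and 1341 lower, with 760 and 596 at least 2-fold, and the median of all genes lay 0.28 higher in OK107. After median centring the split was 1362 and 2073 and after quantile normalization 1809 and 1772. Median centring left 5 acetylcholine receptors, 5 GABA and glutamate receptors, 7 voltage-gated ion channels, 5 cAMP and memory genes and 7 neuronal transcription factors higher. Muscle genes lower in OK107 numbered 13 after median centring, 11 after quantile normalization, 12 with spike-in status and 13 with the date tag as a term. The date tag as a term also gave 15 neuropeptide genes higher. It turned the medians relative to all genes from 0.05 to -0.02 for neuropeptide genes and from -0.05 to 0.19 for serotonin receptors. The count was 1311 and 1331 without OK107 replicate a and b. OK107 a and Tdc2 a share date tag and spike-in status, and between these libraries alone the medians above all genes were 1.44 for Kenyon cell markers and 1.09 for dopamine receptors, and fell by 2.46 for fat body, 1.12 for photoreceptor and 1.26 for ribosomal protein genes.

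**Figure D3:**
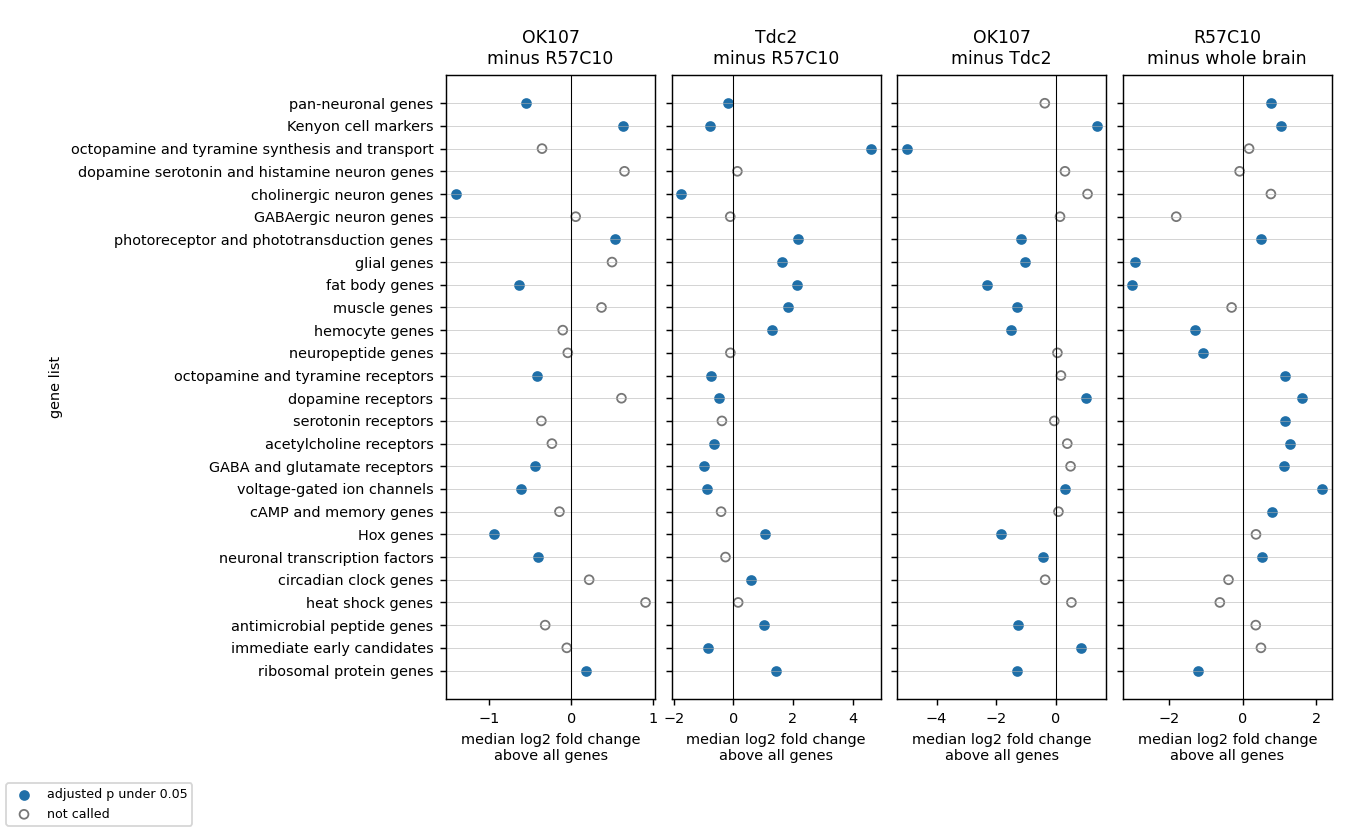
Median log2 fold change of each gene list (rows) minus the median of all genes in the 4 comparisons (panels); filled points passed camera with a preset correlation of 0.01. The octopamine list lies 4.62 above all genes in Tdc2 minus R57C10, and the glial and fat body lists lie near -3 in R57C10 minus whole brain.

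The comparison of R57C10 with whole brain sets tagged neuronal nuclei against the dissected brain, with 1 library of each. The spread is taken from the OK107 and Tdc2 pairs. Preparation, cell content, the nuclear origin of the RNA and the share of each sex cannot be told apart in it. Channel genes were higher in the neuronal nuclei: para was at 547 FPKM against 48.7 (3.46, SE 0.20, adjusted p = 0.000577), Shab (3.08, SE 0.17), cac (2.58, SE 0.19) and SK (2.38, SE 0.16) were also higher. Of the voltage-gated ion channels 19 of 19 were higher (19 higher adjusted over the list alone, camera adjusted p = 5.44e-10, and adjusted p = 0.502 with an estimated correlation). Receptor genes were higher too. Of the acetylcholine receptors, with nAcRalpha-30D (2.41) and nAcRbeta-64B (1.89), 10 of 11 were higher and 1 lower (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000302, and adjusted p = 0.481 with an estimated correlation). Of the GABA and glutamate receptors, with Rdl (2.14) and GluClalpha (1.82), 11 of 13 were higher and 2 did not pass (11 higher adjusted over the list alone, camera adjusted p = 5.13e-05, and adjusted p = 0.502 with an estimated correlation). Among dopamine receptors, with DopR2 (1.92), 4 of 4 were higher (4 higher adjusted over the list alone, camera adjusted p = 0.00312, and adjusted p = 0.431 with an estimated correlation). Among serotonin receptors, with CG42796 (1.21), 5 of 5 were higher (5 higher adjusted over the list alone, camera adjusted p = 0.00496, and adjusted p = 0.444 with an estimated correlation). Among octopamine and tyramine receptors, with Octbeta3R (1.91), 7 of 8 were higher and 1 lower (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00587, and adjusted p = 0.534 with an estimated correlation).

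Glial genes were lower in R57C10: Gs2, the glutamine synthetase gene, was at 36.8 FPKM against 1419.7 (-5.23, SE 0.14), nrv2 at 35 against 1474 (-5.36, SE 0.26), wrapper (-4.40, SE 0.20) and bnb (-3.14, SE 0.15) were lower. Of 14 tested, 1 was higher, 12 lower and 1 did not pass (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 8.68e-05, and adjusted p = 0.466 with an estimated correlation). The GABA transporter gene CG1732 (now Gat) was lower by a log2 change of -5.66 (SE 0.29). In the GABAergic neuron list Gad1 was lower too (-2.02). Of 3 tested, 2 were lower and 1 did not pass (2 lower adjusted over the list alone, camera adjusted p = 0.0612). In the fat body list Obp44a (25.4 against 2985 FPKM, -6.82, SE 0.15), Adh (-4.65) and Yp3 (-3.74) were lower. Of 13 tested, 10 were lower and 3 did not pass (12 lower adjusted over the list alone, camera adjusted p = 0.000139, and adjusted p = 0.429 with an estimated correlation). Hemocyte genes such as the collagen genes Cg25C (-4.41) and vkg (-3.93) were lower. Of 7 tested, 5 were lower and 2 did not pass (6 lower adjusted over the list alone, camera adjusted p = 0.0344, and adjusted p = 0.444 with an estimated correlation). Genes of detoxification and metabolism Ugt35b (-5.69), Cyp28d1 (-5.19), Cyp4g15 (-5.01), MtnA (-5.60), b (-5.02) and Csas (-5.10) were lower, as were Tsp5D (-5.17), Rh50 (-5.04), vir-1 (-5.03), CG9377 (-6.80) and CG8369 (-6.51).

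Peptide and ribosomal protein genes were lower in the neuronal nuclei. Ilp5 (-4.26, SE 0.21), Ilp3 (-3.44, SE 0.17), Dsk (-3.06, SE 0.15) and Ilp2 (-2.76, SE 0.14) were lower. Of the neuropeptide genes 2 of 29 were higher, 21 lower and 6 did not pass (2 higher and 21 lower adjusted over the list alone, camera adjusted p = 0.000746, and adjusted p = 0.431 with an estimated correlation). Of the ribosomal protein genes, such as RpS15 (-1.73), 1 of 86 was higher, 82 lower and 3 did not pass (1 higher and 84 lower adjusted over the list alone, camera adjusted p = 3.04e-13, and adjusted p = 0.466 with an estimated correlation). Of the pan-neuronal genes 10 of 20 were higher, 6 lower and 4 did not pass (10 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0372, and adjusted p = 0.444 with an estimated correlation). Of the Kenyon cell markers 12 of 20 were higher, 2 lower and 6 did not pass (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000831, and adjusted p = 0.429 with an estimated correlation), with rad (2.09) and ey (1.73) higher. cAMP and memory genes (9 of 17 were higher, 2 lower and 6 did not pass, 9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00695, and adjusted p = 0.502 with an estimated correlation) and neuronal transcription factors such as chinmo (1.59) and br (1.73) (19 of 48 were higher, 5 lower and 24 did not pass, 19 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00633, and adjusted p = 0.431 with an estimated correlation) were higher on balance. Photoreceptor genes went both ways, with chp higher (1.98) and Rh2, the opsin gene of the ocelli, lower (-4.50). Of 28 tested, 10 were higher, 3 lower and 15 did not pass (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0242, and adjusted p = 0.431 with an estimated correlation). The mitochondrially encoded list, with mt:ATPase6 lower (-2.05), did not pass (adjusted p = 0.241). Of 3 tested, 2 were lower and 1 did not pass (2 lower adjusted over the list alone).

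The 4 Hsp70B copies gave some of the largest positive differences: Hsp70Bb was at 325 FPKM against 5.86 (5.57, SE 0.27), and Hsp70Ba (4.16), Hsp70Bc (3.95) and Hsp70Bbb (3.90) were higher. These copies are nearly identical, so the share of each is uncertain. Other heat shock genes such as Hsp67Bc were lower (-4.54, SE 0.25). Of the heat shock genes 5 of 15 were higher, 8 lower and 2 did not pass (6 higher and 8 lower adjusted over the list alone). The list did not pass (adjusted p = 0.839), and its median lay below all genes while camera's direction was up. The marker genes of fly transgenes w (26.3 against 0.431 FPKM, 4.26, SE 0.23) and y (19.3 against 0.547, 3.71, SE 0.18) were higher; with 2 members they were not tested as a list. ImpL3 (4.44, SE 0.14), CG6912 (6.13, SE 0.15), CG42810 (5.47, SE 0.15), esc (3.74), KP78b (3.77), the chemosensory genes Obp85a (4.24), Or45a (4.20) and Gr47a (3.64), and Cpr11B (3.71) were higher. Among nuclear-retained noncoding RNA genes, too few for a list test, roX1 was at 6.27 FPKM against 0.0122 (2.84, SE 0.19) and Hsromega at 11.4 against 1.96 (2.06, SE 0.58). roX1 is also a gene of the male X chromosome complex, so its rise is not separated from a difference in the share of each sex.

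In this comparison 5295 of 9605 genes passed in limma, 2140 higher in R57C10 and 3155 lower, with 1391 and 2053 at least 2-fold; the median of all genes fell by 0.22. After median centring the split was 3078 and 2068, after quantile normalization 2461 and 2068, and without mitochondrially encoded and ribosomal RNA genes 3101 and 1894. Under either scaling 6 heat shock genes were higher and 5 lower, and quantile normalization left 2 pan-neuronal genes lower. Both libraries share date tag and spike-in status. The date tag as a term therefore left the fold changes as they were, and counts under it differ only through the spread.

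The isoform table gave relative use of 7913 isoforms of 2684 genes in the tagged nuclei; isoform levels estimated from 50-base reads are uncertain. Between OK107 and R57C10 91 genes passed, between Tdc2 and R57C10 182, and between OK107 and Tdc2 359 (limma diffSplice, adjusted p under 0.05). Shares below are of the summed FPKM of a gene's tested isoforms, and each adjusted p is of the gene, not of the isoform named. para-RAP, an isoform of the sodium channel gene, held 9.18% and 12.7% of this sum in OK107, 1.35% in R57C10, and 0.118% and 0.00211% in Tdc2 (adjusted p = 0.0011 against R57C10 and 4.76e-07 against Tdc2). Ca-beta-RI, of a calcium channel subunit gene, held 22% and 27.2% in OK107, 3.5% in R57C10, and 2.08% and 3.45% in Tdc2 (adjusted p = 0.00226 against R57C10). cpx-RL, of the complexin gene, held 9.90% and 6.36% in Tdc2, 0.569% in R57C10, and 0.522% and 0.595% in OK107 (adjusted p = 1.87e-08 between Tdc2 and R57C10). 14-3-3zeta-RA held 15.8% and 30.5% in Tdc2 and was listed at 0 in R57C10 and OK107. Tequila-RC held 31.6% and 36.4% in Tdc2 against 90.0% in R57C10 and 87.7% and 86.5% in OK107, MED31-RB 21.6% and 21.7% in Tdc2 and under 0.01% elsewhere, and norpA-RB 19.7% and 18.4% in Tdc2 against 0.17% in R57C10 and 4.64% and 4.18% in OK107. norpA is a phototransduction gene, and the photoreceptor, fat body and glial lists lay 2.16, 2.13 and 1.63 above all genes in Tdc2 against R57C10. Isoform shares in Tdc2 are not separated from this rise. These calls rest on few libraries: leaving out OK107 replicate a or b left 1 and 0 genes between OK107 and R57C10 (limma; 254 and 253 at an unadjusted p under 0.05), 37 and 28 between Tdc2 and R57C10, and 39 and 21 between OK107 and Tdc2.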

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

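Spike-in RNA was read in species that none of the comparisons use. Of 92 listed species 60 were above 0 in R57C10, 70 in OK107 b, 65 in Tdc2 b and 58 in whole brain. Their summed level was 1157 FPKM in R57C10 (0.409% of all FPKM), 8475 in OK107 b (2.62%), 3279 in Tdc2 b (1.06%) and 884 in whole brain (0.228%). All 92 species were listed at 0 in OK107 a and Tdc2 a, which served as controls without spike-ins. What set the amounts apart was not tested.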

How the results depend on the processing

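Spike-in status and date tag as terms, and the scalings of the lists, were tried only after the results were seen. With a 2-fold minimum the counts were 1146 for OK107 and R57C10, 1815 for Tdc2 and R57C10, 1356 for OK107 and Tdc2, and 3444 for R57C10 and whole brain, since fewer genes can meet both conditions. Quantile normalization gave 1422 genes for OK107 and R57C10. Only the 2 groups compared gave 5746 for OK107 and R57C10 and 2185 for Tdc2 and R57C10. The date tag as a term gave 5164 for Tdc2 and R57C10. Leaving out 1 library gave from 481 (without OK107 replicate b) to 5712 (without Tdc2 replicate b) genes for OK107 and R57C10, from 2136 (without OK107 replicate a) to 5702 (without Tdc2 replicate b) for Tdc2 and R57C10, and from 1311 (without OK107 replicate a) to 6241 (without Tdc2 replicate a) for OK107 and Tdc2. In these fits the spread comes from the pair that remains, and the lone library is assumed to vary like it. The Tdc2 pair varied more, with an SD of log2 ratios of 0.49 against 0.19 in the OK107 pair between 100 and 1000 implied reads and 0.35 against 0.10 between 1000 and 3000. Counts fell where the Tdc2 pair alone set the spread and rose where the OK107 pair did, which these spreads account for in direction. The other alternatives were within 1.5 times of each count, which does not mean that the same genes passed. After median centring 2354 genes passed for OK107 and R57C10, of which 1133 had also passed in the main fit. This overlap was 3232 of 4058 for Tdc2 and R57C10, 2703 of 3435 for OK107 and Tdc2, and 4208 of 5146 for R57C10 and whole brain.

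For the gene lists, 60 of 105 tests passed camera. With a correlation estimated per list 0 passed (9 at an unadjusted p under 0.05, smallest adjusted p = 0.429). That form has only the 2 residual degrees of freedom to draw on, so this outcome was close to fixed in advance. Another test, fry, which tests a list against no change and not against other genes, passed 57, of which 43 are among the 60. Muscle genes, with an estimated correlation of 0.95, passed camera but not fry in Tdc2 against R57C10 (fry adjusted p = 0.104). The same held in OK107 against Tdc2 (fry adjusted p = 0.168). Between 58 and 66 passed under the scalings, terms and omissions. Lists that passed in both kept their direction under each of these.

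Isoform use was less stable. For OK107 and R57C10 it gave 138 and 139 genes with pseudocounts of 0.1 and 5 and 22 with spike-in status as a term. Without OK107 replicate b it gave 0 (limma, 253 at an unadjusted p under 0.05), and without Tdc2 replicate a 200. For Tdc2 and R57C10 it gave 44 with spike-in status as a term, and from 28 (without OK107 replicate b) to 396 (without Tdc2 replicate b). For OK107 and Tdc2 it gave 198 with spike-in status and 546 with the date tag as a term, and from 21 (without OK107 replicate b) to 494 (without Tdc2 replicate b). The cause was not tested.

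Of 535 values of named genes 369 kept their side of the threshold, and their direction where they passed, under every alternative that could be fitted: 59 of 136 for OK107 and R57C10, 108 of 132 for Tdc2 and R57C10, 90 of 131 for OK107 and Tdc2, and 112 of 136 for R57C10 and whole brain. Across 8165 values under alternatives 7630 did so, 225 passed where they had not, 307 no longer passed and 3 reversed. A change of sign was counted as reversed only where the gene passed in the main fit or under the alternative. Genes that passed in neither may have changed direction uncounted. 5-HT2 between OK107 and R57C10 was 0.43 with the date tag as a term. n-syb between R57C10 and whole brain was 0.83 under quantile normalization. ple between OK107 and Tdc2 ranged from -0.24 without Tdc2 replicate a to 0.72 without Tdc2 replicate b. None of these had passed before, and the cause was not tested.

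No paired analysis was possible because the columns carry no replicate numbers. The nearest fit, spike-in status as a term, sets OK107 a beside Tdc2 a and OK107 b beside Tdc2 b and gave 4425 genes for OK107 and Tdc2 with 1 residual degree of freedom. A fit of R57C10 and whole brain alone was not run, since it leaves no residual degrees of freedom. The depth of each library is known only as an estimate.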

Other observations

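All tests in this part were chosen only after the results were seen. roX1, a noncoding RNA gene of the male X chromosome complex, was at 0.0122 FPKM in whole brain and from 3.53 to 7.15 in the tagged nuclei. fit, a female-biased gene of the head, was at 25.1 in whole brain, 5.89 and 4.71 in Tdc2, and no more than 0.543 in R57C10 and OK107. Levels of cuticle genes were unequal within the Tdc2 pair, at 7.41 and 53.0 FPKM for Acp1 and 6.58 and 35.5 for verm. These genes were picked for their values.

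Photoreceptor, glial, fat body, muscle and hemocyte lists were higher in Tdc2 than in R57C10. RNA from other head cells may have been carried along, and this stays open: the 5 medians above all genes, 1.24 to 2.43 in the Tdc2 libraries, only restate the pattern and do not test it. Levels in the Tdc2 pair were high for abundant genes, with ninaE at 4829.5 and 4054 FPKM, Yp1 at 4104 and 3428 and Gs2 at 268 and 285. A batch of date tag or spike-in status is argued against, since the smallest median was still 1.24 between Tdc2 b and R57C10, which share both. Nuclei were selected by their tag; R57C10 itself had at least 1 FPKM of 27 of 28 photoreceptor, 13 of 14 glial, 11 of 13 fat body, 13 of 17 muscle and 6 of 7 hemocyte genes, and no member is on another list. GAL4 activity in other cells stays open and was not tested.

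The Hsp70B copies and w were higher in R57C10 than in whole brain. The 11 other heat shock genes had a median of -1.49 (SD 1.69) while the copies were at 3.90 to 5.57, so they did not share the rise. A heat response stays open all the same. Tagged nuclei are set against dissected tissue, and genes can be lower in the nuclei for that reason, as 82 of 86 ribosomal protein genes were. Photoreceptor genes had a median of 0.28 (SD 1.25), far below w at 4.26, so they did not share its rise. Eye tissue outside the dissected brain stays open all the same. Pigment cells were not tested, and here too nuclei are set against dissected tissue. Transgene-derived sequence may contribute, and this stays open. w was 61.2 to 350.0 times and y 8.27 to 35.3 times as high in the 5 tagged libraries as in whole brain, but the ratios for R57C10 restate the pattern and all of them share 1 whole brain library, so they do not test it. The labels name the unc84-GFP transgene and GAL4 lines but no marker genes. These ratios cover w and y and not the Hsp70B copies, and other biological explanations were not tested.

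Yolk protein genes were lower in OK107 than in Tdc2. The 10 other genes of the fat body list fell less, with a median of -1.58 (SD 1.33, from -4.09 to 0.49) against -7.28 to -6.31 for Yp1, Yp2 and Yp3. The part of fat body stays open, since that list does not measure fat body alone. It holds Cyp4g1, named above as a gene of oenocytes. Date tag or spike-in batch is argued against by falls of -6.31 to -7.44 between OK107 a and Tdc2 a, which share both. A difference in the share of each sex may contribute, and this stays open. Of 7 sex-biased genes listed, 5 passed the filter and all 5 went the way a larger share of males in OK107 would give, but values of roX1, roX2, to, Cyp4d21 and fit had been seen before they were listed. The list and the number of genes required were both changed afterwards, so the count does not test it. Obp99b, a male-biased gene under the filter, went the other way, at 0.124 and 0 FPKM in OK107 against 0.151 and 1.09 in Tdc2, and the labels used here give no sex.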
